A study of Homo sapiens with 15 samples.

How the data were processed

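Single cells of 7 primary Ewing sarcomas and 8 blood samples were profiled by 3' droplet libraries of polyadenylated RNA. Per the labels' protocols, tissue was thawed, digested with collagenase and DNase, strained, depleted of red cells and sorted for DAPI-negative, that is intact, cells. The labels attach the same text to the blood samples, and how blood was prepared is not given separately in the sources used here. The authors' names of the blood libraries end in CTC. What this means for the choice of cells from blood is not given there either. Reads were processed with Cell Ranger 6.0.1 against GRCh38 and analysed with Seurat, per the submitters' processing notes, which give no version of Seurat. Reads were not used here.

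The authors deposited raw UMI counts per gene and cell, 1 table for tumors and 1 for blood, with 22639 genes each. The deposited matrix of 20 aggregated libraries holds counts for 36601 genes, per the file headers. Whether reads were subsampled at aggregation is not given in the sources used here. Over the genes whose name belongs to 1 feature, 22624 in each table, the deposited tables and the filtered matrix were equal count by count, and in all 6228 tumor and 7139 blood cells the counts summed to the total in the cell table. Of the aggregated libraries 5 belong to no listed sample; their 29150 barcodes were not used. The authors' deposited cell tables give each cell's library, class, subclass, total count and percent of mitochondrial counts, the SCEVAN call (malignant or normal, from inferred copy number) and, for Ewing cells, program scores that are standardised scores made by the authors. All kept cells are singlets of scDblFinder and have at most 20% mitochondrial counts, per the deposited cell tables, so no doublet caller was run again. The median percent of mitochondrial counts per library, from the deposited percent values, was 2.23 to 6.62 in tumors and 1.72 to 9.16 in blood.

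The library was the replicate throughout. Samples were grouped as primary tumor or blood by the labels, and libraries are numbered within each group. Cell classes were the authors'. The main tests, gene lists, cell type markers and the rule for named genes were fixed before the data were examined; tests chosen later are given as such. Shares were compared by a two-sided exact permutation test of the difference of means. Immune shares used libraries with at least 50 immune cells and were adjusted over 4 classes (Benjamini-Hochberg). The authors' T class also holds natural killer cells in blood, so these were not compared apart, and plasma cells and neutrophils had no class of their own.

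For gene tests, raw counts were summed per library and class where a class had at least 20 cells. The sums were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment, threshold 0.05) under R 4.3.3. Ewing cells were compared with all other cells of the same 6 tumors with the tumor as a block. T cells of 5 tumors were compared with those of 8 blood samples, and monocytes or macrophages of 3 tumors with those of 5 blood samples, without a block. The blood comparison of Ewing cells had 1 library and was not tested. Levels are the summed counts scaled to a total of 1000000 (CPM), with SDs over libraries; log2 fold changes and their SEs are edgeR's. For a gene with a count of 0 in a group, the limit is 3 counts over the group's UMIs. For 1 to 3 counts, the ratio of pooled levels has an exact 95% interval from the binomial split of the counts. The 21 fixed gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists with at least 3 measured members. Camera with an estimated correlation and fry were alternatives. Adjusted over the list alone means Benjamini-Hochberg over a list's own measured genes. Counts do not split reads of near-identical copies. Strand use at counting is not given in the sources used here, so no antisense gene is named.

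Named genes were, in each comparison, the 12 largest rises and 12 largest falls among genes past the threshold with a log2 change of at least 1 and at least 32 CPM in the higher group, up to 4 measured members of each list with the smallest p, and EWSR1, FLI1 and CD99. Of the genes so named, antisense genes apart, 2 are not reported here. Between tumors they were the 12 with the largest SD of log2(CPM + 1) at 50 CPM or more. Immunoglobulin and T cell receptor segments, sex-linked markers, mitochondrial and ribosomal genes and unnamed transcripts were left out. Gene positions come from GENCODE 29 on GRCh38, in which 34616 of the 36601 gene IDs were found.

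Scores within tumors used 6 tumors with at least 100 Ewing cells of 2000 UMIs or more. Each cell was thinned to 2000 UMIs, the score was the mean log count of a list, and rank correlations over cells were tested across tumors by a two-sided exact sign-flip test of Fisher z. Scripts ran on Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9.

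The gene test was tested on simulated data with 200 changed genes for each comparison. Among 10056 genes of the Ewing comparison it recovered 4% of changes of 1 and 75% of changes of 2 on the log2 scale, with 1 false of 80 calls. For T cells, with 3544 genes, it recovered 12% and 68%, with 1 false of 81 calls, and for monocytes or macrophages, with 1529 genes, 6% and 67%, with 2 false of 75 calls. With 200 genes changed, most changes of 2-fold were therefore not called in the simulated data. The real Ewing comparison called 2696 genes, which makes its adjusted threshold less strict. This recovery need not hold there. The simulated data held no difference between the kinds of library described below, so the false calls do not cover one.

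Pairing comes from the labels, which place a tumor and a blood sample with the same patient for 4 patients. Deviations of T cell profiles from their group means correlated at 0.178 on average between samples of the same patient (4 pairs, from 0.00693 to 0.486) and at -0.0613 between different patients (12 pairs). Within barcode set 2 it was 0.0754 (3 pairs) and 0.0857 (6 pairs), so the profiles there gave no support to the pairing. Raw barcodes showed 2 kinds of library: those of set 1 had at least 58.4% of their raw barcodes in common with the library with the most barcodes, those of set 2 at most 5.10%. The labels give no batch, so the set served as one, chosen after seeing the data.

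Besides, the tests were repeated with DESeq2 1.42.0, DESeq2's size factors in edgeR, no filter on low counts, at least 50 cells per sum, leaving out the 200 most abundant genes of empty droplets, leaving out each library, the patient block, clusters named by fixed markers, a filter of 1000 UMIs and 10% mitochondrial counts, thinning to 1000 UMIs, unthinned scores, cells without TOP2A and MKI67 UMIs and a prior count of 10. After the data had been seen, they were repeated with the barcode set as a covariate, tests within a set, cells whose barcode was called in 1 library, leaving out genes at least 4 times higher in Ewing cells, the paired patients without a block, leaving out each tumor from the spreads, leaving out each library from limits at 0 counts and ratios at 1 to 3 counts, and splits within set 2. Copy number profiles and sequence variants of single tumors were not analysed here.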

Results

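Ewing sarcoma is a malignant tumor of bone and soft tissue whose cells usually carry a fusion of EWSR1, an RNA-binding protein gene, with FLI1, an ETS transcription factor gene. The study characterised the tumors cell by cell, without treatment. Polyadenylated RNA of single cells was counted in droplets from 15 samples of 11 patients, namely 7 primary tumors and 8 blood samples, and 4 patients gave both. The deposited tables held 6228 tumor cells with 98936678 unique molecular identifiers (UMIs, each standing for 1 captured RNA molecule) and 7139 blood cells with 9371019 UMIs. A tumor cell had a median of 13790.5 UMIs and a blood cell 1055. Tumors 1 to 7 held 3538061, 26309613, 7105549, 2371763, 710969, 53701204 and 5199519 UMIs, in 388, 1580, 929, 794, 56, 2143 and 338 cells. Blood samples 1 to 8 held 483430, 2203070, 1011911, 528055, 1081497, 440365, 286663 and 3336028 UMIs, in 192, 895, 882, 338, 887, 192, 159 and 3594 cells. Each library stands for 1 sample, so the replicate was the patient's sample and cells were not treated as replicates. The cell barcodes fell into 2 sets, which mark 2 kinds of library that the labels do not name. Set 1 held tumors 4 to 7 and blood 8, and set 2 held tumors 1 to 3 and blood 1 to 7. Intervals and limits given below cover counting error only.

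The first comparison asked which cells the tissue and the circulation held. How cells of blood were chosen is not given, so the blood shares may not be those of whole blood. Ewing cells, as the authors annotated them, made up 78.8% ± 19.0 of a tumor's cells (SD, n = 7), from 41.2% to 96.5%. In blood the mean was 2.23% ± 6.29 (SD, n = 8), and all of those cells lay in 1 library. The difference passed a two-sided exact permutation test (p = 0.0003108). The tumors also held 488 T cells, 174 monocytes or macrophages, 141 fibroblasts, 68 endothelial cells, 50 dendritic cells, 34 B cells and 20 osteoclasts, the cells that resorb bone. Fibroblasts were seen in 4 tumors and made up 27.6% of tumor 1. Blood held 3843 T cells, 2339 monocytes, 257 dendritic cells, 246 platelets, 204 B cells and 93 erythrocytes beside 157 cells annotated as Ewing cells. Of the tumor cells that the authors called by copy number with SCEVAN, 89.0% of the annotated Ewing cells were called malignant, as were 18.75% of osteoclasts (3 cells), 9.52% of B cells (2 cells), 0.294% of T cells and 0.84% to 4.76% of the other classes.

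Among immune cells, dendritic cells, which present antigen to T cells, took a larger share in the 4 tumors with enough immune cells than in blood. Their share was 9.11% ± 5.73 (SD, n = 4) against 1.05% ± 2.54 (SD, n = 8), with p = 0.0121 in an exact permutation test and 0.0485 after adjustment over 4 classes. The call was lost without tumor 1, 3 or 4 (6.43 to 7.93 points, adjusted p = 0.145), without any of blood 2 to 7 (7.92 points, adjusted p = 0.0727) and with a filter on UMIs and mitochondrial counts (8.70 points, adjusted p = 0.424). The dendritic class also differed in kind: all 50 cells of tumors were of a CD1C subclass, whereas 143 of the 255 in blood 8 were plasmacytoid. T cells made up 53.5% ± 27.5 of immune cells in those tumors and 77.4% ± 18.2 in blood (exact permutation test, adjusted p = 0.242). Monocytes or macrophages made up 30.9% ± 19.0 and 16.2% ± 16.9 (exact permutation test, adjusted p = 0.248), and B cells 6.52% ± 4.01 and 5.38% ± 4.62 (exact permutation test, adjusted p = 0.614). Clusters named by fixed markers gave no check of it (-0.566 percentage points), because no cluster of tumor cells was named dendritic and the share of the tumors was therefore 0. It turned to -2.01 points within barcode set 1, where the only blood library was blood 8, and was 12.8 points within set 2, where no result could pass (exact permutation test, p = 0.0556, the smallest that 2 against 7 allow).

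**Figure D1:**
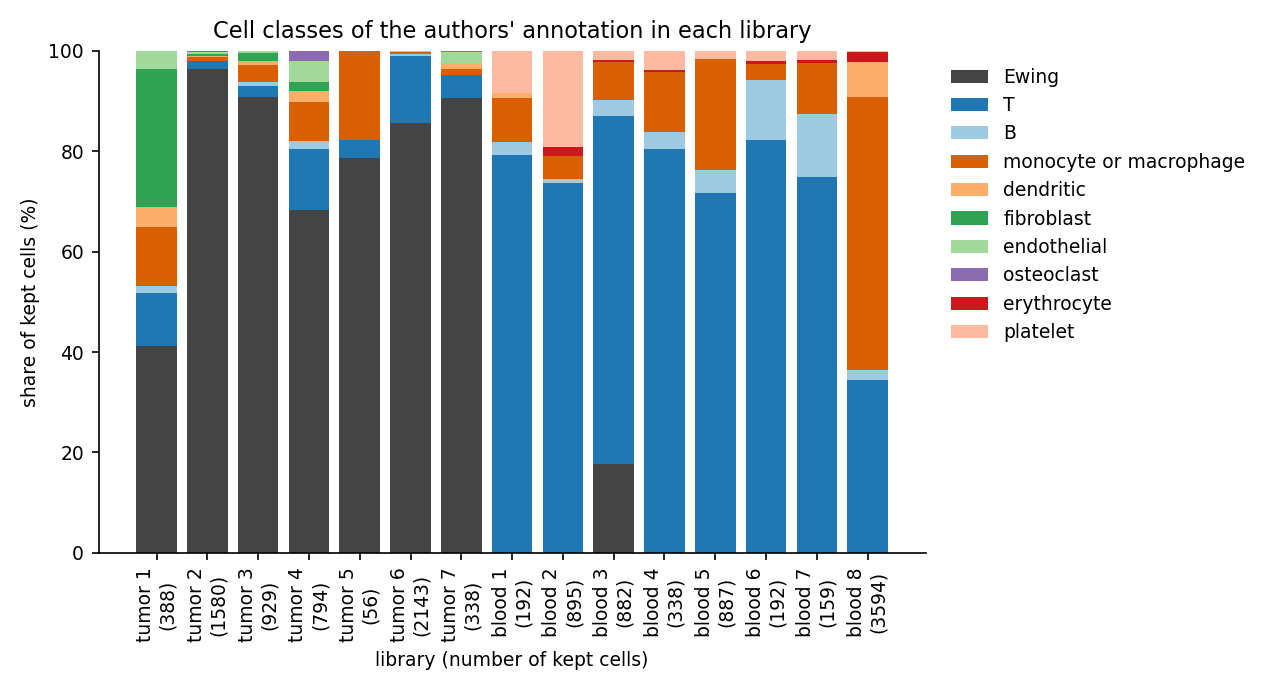
Percent of cells in each annotated class for each library, tumors and blood, 1 stacked bar per library. Ewing cells filled 41.2% to 96.5% of the tumor bars, and of the blood bars 1 holds them, at 17.8%.

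The next comparison asked which genes set the malignant cells apart from the other cells of the same tumors. Of 22 measured EWSR1::FLI1-activated genes 21 rose in Ewing cells. UGT3A2, a glycosyltransferase gene, led at 261 ± 328 CPM (counts scaled to a total of 1000000) against 1.75 ± 2.73 (SD, n = 6 tumors). Several, UGT3A2 among them, are also markers of Ewing cells, so their rise may partly restate the annotation, which rests on expression. In the cell cycle 13 of 21 G2/M and 7 of 17 S phase genes rose. In antigen presentation 11 of 13 measured MHC class I genes and all 10 MHC class II genes fell, as did 8 of 21 matrix and mesenchymal genes. None of the calls of these 6 lists held with an estimated correlation (adjusted p = 0.0721 to 0.297). The other cells were a mix that differed by tumor. In tumor 6, 286 of 309 were T cells, and in tumor 1, 107 of 228 were fibroblasts. A fall is relative to that mix and does not by itself mean reduced antigen presentation or matrix expression in Ewing cells. Of 10056 genes tested in 6 tumors with the tumor as a block, 1289 rose and 1407 fell (edgeR quasi-likelihood test, adjusted p below 0.05).

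The largest rise was that of UGT3A2, by 7.03 ± 0.59 on the log2 scale (SE, edgeR adjusted p = 2.72e-05). BEX1, a brain-expressed adaptor, rose by 6.18 ± 0.49 (edgeR adjusted p = 2.23e-05) and CLVS2, which binds lipid in neuronal vesicles, by 6.16 ± 0.38 (edgeR adjusted p = 9.41e-06). Log2 rises of 5.59 to 5.96 were measured for ADRB3 (5.96), the beta-3 adrenergic receptor, CSPG5 (5.86), a neural proteoglycan, PCDH11X (5.83), a protocadherin, PAPPA (5.81), a protease that cleaves IGF-binding proteins, TSPAN8 (5.77), a tetraspanin, PPP1R1A (5.63), an inhibitor of protein phosphatase 1, HOOK1 (5.60), a microtubule linker, DCC (5.59), a netrin receptor, and AMER2 (5.59), a regulator of Wnt signaling. On GRCh38, UGT3A2 lies on chromosome 5 from 36035017 to 36071358 and PPP1R1A on chromosome 12 from 54575387 to 54588659.

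Among the activated genes, NR0B1, a nuclear receptor on chromosome X from 30304206 to 30309598, rose by 5.28 and RBM11, a splicing factor, by 5.21. All 21 also passed when adjusted over the list alone, with a list median of 4.38 (camera adjusted p = 4.70e-11), a call lost with an estimated correlation (adjusted p = 0.0721). Of 10 measured genes reported as repressed by the fusion, 1 fell: TGFBR2, the type II TGF-beta receptor on chromosome 3 from 30606502 to 30694142, by -7.22 on the log2 scale (edgeR adjusted p = 9.21e-05). It was also the only one adjusted over the list alone, and the list's median of -0.81 did not pass (camera adjusted p = 0.165). The fusion partners themselves were not higher in Ewing cells. FLI1 was lower, at 17.4 ± 13.1 against 41.3 ± 25.2 CPM (log2 -1.43 ± 0.45, edgeR adjusted p = 0.0430), a call lost when tumor 2, 3, 4, 6 or 7 was left out (log2 -1.52 to -1.45), while EWSR1 was at 58.4 ± 16.1 against 90.3 ± 18.3 CPM (log2 -0.55, edgeR adjusted p = 0.0769). Counts of a 3' assay do not separate the fusion transcript from the normal FLI1 transcript, which endothelial and blood cells express. CD99, the surface protein used to diagnose Ewing sarcoma, was at 546 ± 179 CPM in Ewing cells and 545 ± 310 in the others (edgeR adjusted p = 0.658).

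Of 21 measured G2/M genes 13 rose, 15 when adjusted over the list alone, such as CKS1B (log2 1.69), CDK1 (1.97), the kinase that starts mitosis, NUSAP1 (2.35) and TPX2 (1.92), both of the spindle. Of 17 S phase genes 7 rose, 10 when adjusted over the list alone, including TYMS (3.04), an enzyme of thymidylate synthesis, RRM1 (1.18) and MCM4 (1.29), whose call was lost without tumor 4. The list medians were 1.72 and 1.27 (camera adjusted p = 1.07e-04 and 4.64e-04). With an estimated correlation neither passed (adjusted p = 0.211 for G2/M and 0.181 for S phase). In hypoxia and glycolysis 4 of 23 genes rose and 1 fell, the same numbers adjusted over the list alone. LDHA, lactate dehydrogenase A, rose by 1.62, MXI1 by 2.05 and BNIP3, a mitophagy receptor, by 2.997, and PFKFB3 fell by 1.65, a call lost without tumor 2, 3 or 4, but the list did not pass as a set (camera adjusted p = 0.362). Of 30 oxidative phosphorylation genes 3 rose and 1 fell (camera adjusted p = 0.476). Of 22 immediate-early and heat-shock genes 1 rose, HSPA8 by 0.98, and 1 fell, HSPA6 by 2.50, with a median of 0.10, a mean of 0.06 and a test direction that was down (camera adjusted p = 0.985). None of 3 measured neural genes passed (camera adjusted p = 0.362), and of 3 red cell and platelet genes 1 rose, GP1BB by 2.66 (camera adjusted p = 0.547).

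Among MHC class I genes HLA-F (log2 -4.22), HLA-B (-3.35), B2M (-1.41), the light chain of class I, and ERAP1 (-2.28), which trims peptides, fell. Of the 13, 12 passed when adjusted over the list alone and the median was -1.56 (camera adjusted p = 2.28e-07). Of class II, CD74 (-7.57), the invariant chain, and HLA-DQB1 (-8.04) fell, all 10 passed adjusted over the list alone, and the median was -7.80 (camera adjusted p = 6.81e-13). With an estimated correlation neither call held (adjusted p = 0.181 for class I and 0.0721 for class II). HLA genes vary between people and resemble each other, so their single values are uncertain. Of 25 interferon-stimulated genes 12 fell, among them IFI27 (-6.14), IFI44L (-4.01), MX2 (-5.58) and EPSTI1 (-4.30), with 14 lower and 1 higher adjusted over the list alone (camera adjusted p = 6.15e-05, or adjusted p = 0.192 with an estimated correlation). Of 21 matrix and mesenchymal genes 8 fell, 9 adjusted over the list alone, such as COL3A1 (-6.63), a fibrillar collagen, FBN1 (-4.52), fibrillin 1, S100A6 (-3.02) and COL6A2 (-4.06), whose call was lost without tumor 2 or 4. Their median was -2.22 (camera adjusted p = 2.73e-04, or adjusted p = 0.297 with an estimated correlation).

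Among the largest falls, MNDA, a nuclear antigen of myeloid cells on chromosome 1 from 158831317 to 158849506, had 3 counts in all Ewing cells and 433 in the other cells, a ratio of 3198 between pooled levels (exact 95% counting interval 1087 to 15568). SAMSN1, an adaptor of B cells, also had 3 counts, with a ratio of 2349 (796 to 11449), as had CYBB, the phagocyte oxidase, with a ratio of 2644 (897 to 12882). MS4A4A had 2 counts and a ratio of 1950 (532 to 16226). Without tumor 1 the ratios of CYBB and MS4A4A were 5323 and 4100, and that of MS4A4A was 3052 without tumor 4 and 1157 without tumor 6. LILRB4, an inhibitory receptor of myeloid cells, had no counts in 93860634 UMIs of Ewing cells, which allows 0.0320 CPM, so it was at least 1034-fold lower than the 33.0 CPM of the other cells, or at least 520-fold without tumor 6 and 686-fold without tumor 4. C1QC (log2 -10.44), a complement component, MS4A7 (-9.75), CSF1R (-9.75), the macrophage growth factor receptor, SAMD3 (-9.69), RGS1 (-9.68), RNASE1 (-9.61) and KLRB1 (-9.604), a lectin receptor of lymphocytes, fell as well. The lists of immune cells followed. All 11 blood monocyte genes fell (median -8.48), as did 9 of 10 inflammatory cytokine genes (-6.26), 8 of 11 naive T cell genes (-4.19) and 6 of 9 tissue-resident lymphocyte genes (-2.46), each past the camera threshold also with an estimated correlation (adjusted p = 0.0408 for each). Of 10 cytotoxic genes 9 fell (adjusted p = 0.0672 with an estimated correlation), and of 18 tumor-associated macrophage genes 13 fell and 1 rose (adjusted p = 0.0891 with an estimated correlation). Of 7 checkpoint genes 3 fell and TOX2, a transcription factor gene, rose by 2.83 (camera adjusted p = 0.0386, or adjusted p = 0.164 with an estimated correlation). Of 4 regulatory T cell genes TNFRSF1B, a TNF receptor, fell by 8.52 (camera adjusted p = 0.372). The annotation itself rests on expression, so rises of Ewing markers and falls of immune markers partly restate how the classes were drawn.

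T cells of the tumors were then set against T cells of blood, which compares lymphocytes in the tissue with those in the circulation. Tumor T cells carried more immediate-early transcripts than those of blood. FOS, a subunit of the AP-1 transcription factor on chromosome 14 from 75278774 to 75282230, was at 1951 ± 982 CPM (SD, n = 5) against 31.6 ± 70.4 (n = 8), and JUN, its partner, at 915 ± 255 against 36.0 ± 71.3. Of 8 genes of tissue residency 6 rose with them, led by RGS1, a regulator of chemokine signaling, while 6 of 15 genes of naive and recirculating T cells fell. Of 3544 genes tested, 155 rose and 173 fell (edgeR quasi-likelihood test, adjusted p below 0.05). The authors' subclasses differed between the tissues: the T class of blood held naive and cytotoxic T or natural killer cells alone, that of tumors resident memory, CD8 effector, CD4 and regulatory T cells, so the test does not separate a change within a subclass from a change of the mix.

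The largest rise was LMNA, a nuclear lamina gene on chromosome 1 from 156082573 to 156140089, by 6.08 ± 0.67 on the log2 scale (SE, edgeR adjusted p = 9.65e-06). RGS1, on chromosome 1 from 192575727 to 192580031, rose by 5.93 ± 0.55 (edgeR adjusted p = 7.46e-07) and IFNG, the cytokine interferon gamma, by 5.63 ± 0.85 (edgeR adjusted p = 1.59e-04). FOS rose by 5.57 ± 0.72 (edgeR adjusted p = 5.82e-05) and JUN by 4.28 ± 0.58 (edgeR adjusted p = 7.56e-05). The others among the 12 were NR4A2 (4.77), a nuclear receptor induced by T cell receptor signals, FOSB (4.73), SERTAD1 (4.54), NEU1 (3.93), a sialidase, DUSP1 (3.77), a phosphatase that acts on MAP kinases, TUBB4B (3.74) and EGR1 (3.70). Of 17 measured immediate-early and heat-shock genes 15 rose, the same 15 in number when adjusted over the list alone, with DNAJA1, a chaperone, at 2.90. The list's median was 2.90 (camera adjusted p = 2.37e-22), and the call held with an estimated correlation (adjusted p = 0.0159). Ewing cells of the tumors carried this list at a mean of 7.87 ± 1.33 log2 CPM (SD, n = 7), tumor T cells at 7.82 ± 0.78 (n = 5) and blood T cells at 4.22 ± 0.86 (n = 8).

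The rises of tissue-resident lymphocyte genes included CD69 (2.05), which keeps T cells in tissue, RGS2 (3.35) and ZNF331 (3.07). The list's median was 2.33 (camera adjusted p = 1.80e-06), with 6 higher and 1 lower adjusted over the list alone. Checkpoint and dysfunction genes held 3 of 6 that rose, also 3 adjusted over the list alone: TNFRSF18 (2.32), or GITR, ICOS (1.94), a costimulator, and TIGIT (1.65), an inhibitory receptor whose call was lost without blood 1, 2 or 7 or any of the 5 tumors (1.47 to 1.82) (camera adjusted p = 0.0016). The naive and recirculation genes that fell, 11 adjusted over the list alone, included MAL, a membrane protein of naive T cells on chromosome 2 from 95025677 to 95053996 (-2.89 ± 0.50, edgeR adjusted p = 6.42e-04), NOSIP (-2.15) and LTB (-1.66), lymphotoxin beta. Their median was -1.31 (camera adjusted p = 2.38e-06). Of 6 matrix and mesenchymal genes 3 rose, 4 adjusted over the list alone, namely ANXA1 (2.54) and ANXA2 (1.17), annexins that bind membranes, the latter without a call when tumor 1 or 6 was left out, and VIM (1.64), an intermediate filament that T cells also express (camera adjusted p = 7.23e-04). These 4 lists kept their calls with an estimated correlation (adjusted p = 0.0159 for residency, 0.0381 for checkpoint, 0.0307 for naive and 0.0307 for matrix genes).

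Cytotoxic genes did not move one way: IFNG and GZMK (2.17), a granzyme, rose and FCGR3A (-3.01), an Fc receptor of natural killer cells, fell among 15, with a median of -0.89 and a test direction that was up (camera adjusted p = 0.936). Of 14 hypoxia and glycolysis genes LDHA (1.55) and SLC2A3 (1.93), a glucose transporter, rose (camera adjusted p = 0.0193, or adjusted p = 0.280 with an estimated correlation). Of 30 oxidative phosphorylation genes COX4I1 (-1.04) and COX6C (-1.02), subunits of cytochrome c oxidase, fell, 4 adjusted over the list alone (camera adjusted p = 0.0288, or adjusted p = 0.802 with an estimated correlation). Of 14 interferon-stimulated genes ISG20 (-1.07) fell (camera adjusted p = 0.657). None of 12 MHC class I genes (camera adjusted p = 0.657) and none of 6 class II genes (camera adjusted p = 0.0593) passed, and of 3 G2/M genes CKS2 (2.56) rose (camera adjusted p = 0.541). None of 3 EWSR1::FLI1-activated and none of 3 repressed genes passed (camera adjusted p = 0.657 for each). EWSR1 (log2 0.52, edgeR adjusted p = 0.396), CD99 (0.27, adjusted p = 0.609) and FLI1 (0.07, adjusted p = 0.9505) did not pass either. Calls were lost for COX4I1, COX6C and ISG20 without any of blood 1 to 7 or tumors 3, 4 and 6, and for COX6C without tumor 1, for FCGR3A without blood 5, tumor 3 or tumor 6 (-3.01 to -1.81), for SLC2A3 without tumor 4 (1.07) and for CKS2 without tumor 2 (2.24).

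PPBP and PF4, chemokines of platelets, had no counts in the 1554496 UMIs of tumor T cells, which allows 1.93 CPM, and were at least 130-fold and at least 44.4-fold lower than in blood. S100A9, a calcium-binding protein of monocytes, was at least 34.4-fold lower and JCHAIN, the joining chain of secreted antibody, at least 23.7-fold lower. S100A8 had 1 count, with a ratio of 67.5 (exact 95% counting interval 12.0 to 2678) between pooled levels. Tumor 6 held 1300697 of these UMIs, and without it the limit was 11.8 CPM, the folds at least 21.3, 7.25, 5.62 and 3.86 and the ratio of S100A8 11.0, and these genes but PPBP lost their calls, as did KLRF1. Without blood 2 PPBP and PF4 were at least 36.6-fold and 17.03-fold lower, without blood 8 S100A9 at least 22.1-fold, without blood 1 JCHAIN at least 15.4-fold and without tumor 1 S100A8 at least 21.2-fold. In empty droplets of blood these 5 genes were at 1248 to 2869 CPM, and T cells of blood were at 2.82% to 8.77% of that, so free RNA in the blood suspensions was not excluded as their source. AIF1, an actin-binding protein (-4.11 ± 0.51, edgeR adjusted p = 4.24e-05), KLRF1, a receptor of natural killer cells (-3.98), and FHIT (-3.51) were also lower. Of 5 measured blood monocyte genes 3 fell, 4 adjusted over the list alone, with a median of -4.18 that was the same with S100A9 at its limit (camera adjusted p = 0.00323, or adjusted p = 0.0720 with an estimated correlation). The number of genes called moved with the libraries: it was 779 without blood 8, 195 without blood 3 (129 rose and 66 fell), 199 without tumor 4, 204 to 216 without blood 2, 4, 5 or 6, 224 with genes of empty droplets left out (134 and 90) and 204 with the patient as a block in the 4 patients with both samples (152 and 52). Within barcode set 2 it was 430, where 17 of 19 immediate-early and heat-shock genes rose, with a median of 3.59, but the falls of PPBP, PF4, S100A8, S100A9, JCHAIN, KLRF1 and FCGR3A did not pass there (edgeR adjusted p = 0.0721 to 0.331).

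**Figure D2:**
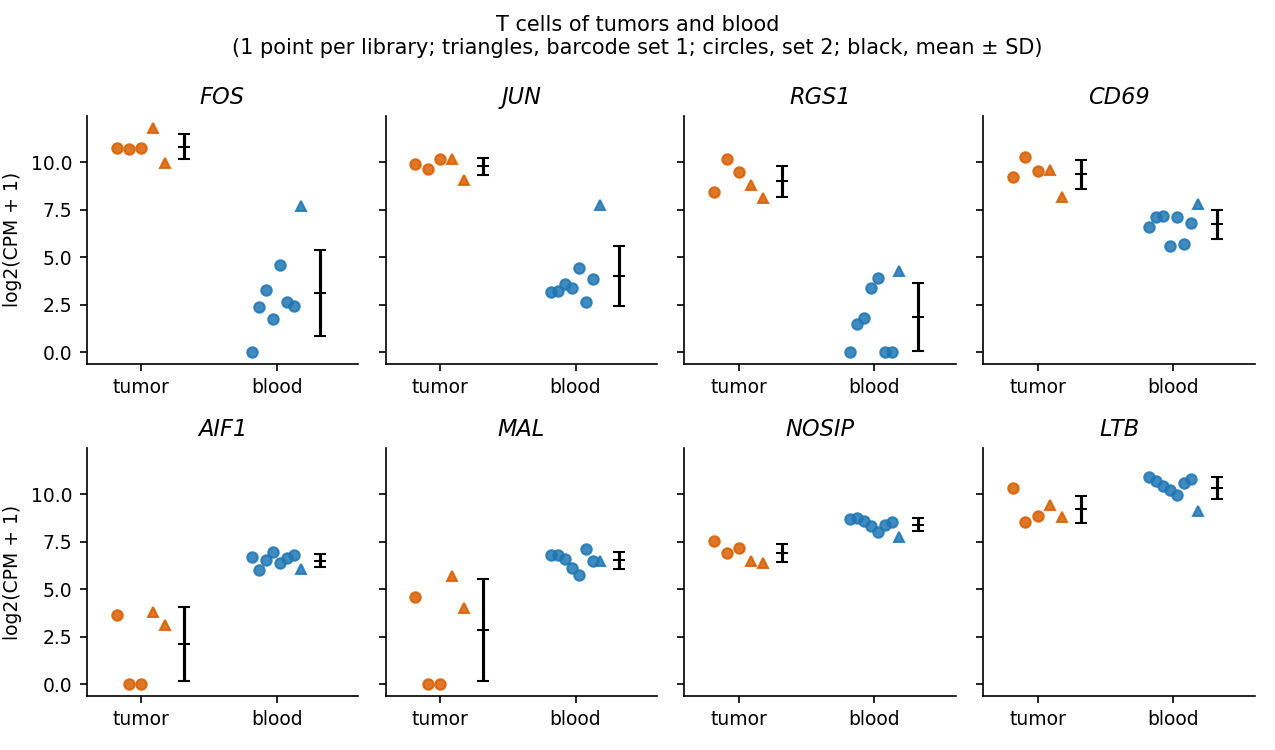
log2(CPM + 1) of 8 genes in T cells summed per library, 5 tumors against 8 blood samples, 1 point per library (triangles, barcode set 1; circles, set 2) with the mean ± SD in black. FOS, JUN, RGS1 and CD69 rose in tumors and AIF1, MAL, NOSIP and LTB fell (edgeR adjusted p below 0.05).

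Monocytes or macrophages of the tumors differed from those of blood in the same kind of test. In tumors 12 of 14 tumor-associated macrophage genes, 7 of 8 inflammatory cytokine genes and 11 of 21 immediate-early and heat-shock genes rose, but no call of these 3 lists held with an estimated correlation (adjusted p = 0.0763, 0.0763 and 0.119). SPP1, or osteopontin, a secreted matrix protein on chromosome 4 from 87975650 to 87983426, reached 4795 ± 3406 CPM (SD, n = 3) against 2.20 ± 4.91 (n = 5). It had 1 count in blood, a ratio of 11092 (exact 95% counting interval 1988 to 438362) between pooled levels, which was 2119 without blood 8, 17820 without tumor 1 and at least 3570 without blood 2. Of 1529 genes tested, 104 rose and 41 fell (edgeR quasi-likelihood test, adjusted p below 0.05). The cells were mostly of other subclasses in the 2 tissues, with complement and inflammatory subclasses in tumors and FCN1 monocytes in blood.

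All 14 macrophage genes rose when adjusted over the list alone. LGMN, a lysosomal protease, rose by 7.25 ± 0.65 on the log2 scale (SE, edgeR adjusted p = 1.22e-05), GPNMB, a transmembrane glycoprotein of lysosome-rich macrophages, by 6.63 and C1QC, of the complement C1 complex, by 6.00. Of the cytokine genes 7 rose adjusted over the list alone, too. CXCL8, the neutrophil attractant interleukin 8, on chromosome 4 from 73740506 to 73743716, rose by 7.94 ± 0.79 (edgeR adjusted p = 1.92e-05), CXCL3 by 9.95, CCL2, the monocyte attractant, by 9.57, CCL3 by 8.21 and CCL4 by 7.01. CXCL2 had 1 count in blood, a ratio of 5061 (905.5 to 200173), or 967 without blood 8, 3144 without tumor 3 and at least 1538 without blood 5. Of the immediate-early and heat-shock genes 17 rose adjusted over the list alone, with ATF3, a stress-induced transcription factor, at 5.21 and DNAJB1 at 4.81. HSPA1B (8.03) and HSPA1A (4.71), inducible HSP70, are near-identical copies whose split is uncertain. The list medians were 3.41 for macrophage, 8.07 for cytokine and 1.68 for immediate-early genes (camera adjusted p = 1.86e-13, 1.44e-12 and 1.86e-13).

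RNASE1, a secreted ribonuclease, rose by 10.08 (edgeR adjusted p below 0.05) and PLTP, a lipid transfer protein, had 2 counts in blood, a ratio of 492 (134 to 4098), or 93.9 without blood 8, 952 without blood 4 and 896 without blood 5. MHC class II genes held 2 of 9 that rose, HLA-DQA1 (2.40) and HLA-DRB1 (2.05), and 5 adjusted over the list alone (camera adjusted p = 0.00184, or adjusted p = 0.322 with an estimated correlation). Of 13 blood monocyte genes 2 fell, MNDA (-1.87) among them, with 9 lower and 1 higher adjusted over the list alone (median -1.65, camera adjusted p = 0.00214, or adjusted p = 0.355 with an estimated correlation). The other large falls were LGALS2 (-3.80), a galectin, WARS (-3.67), the tryptophan tRNA synthetase, CLEC12A (-3.14), an inhibitory lectin receptor of myeloid cells, CDC42EP3 (-3.01), RIPOR2 (-2.86), PLAC8 (-2.85), CX3CR1 (-2.85, edgeR adjusted p = 0.0225), the fractalkine receptor of patrolling monocytes, CDKN2D (-2.84) and NCF1 (-2.80), an oxidase subunit with near-identical pseudogenes. PPBP, a platelet gene, had 1 count in tumors. It was lower by a ratio of 69.0 (12.3 to 2733), or 39.1 without tumor 1 and at least 15.6 without tumor 4. In empty droplets of blood PPBP was at 2869 CPM, against 203 CPM in blood monocytes. Free RNA in the blood suspensions was therefore not excluded as its source. LTB had 3 counts and a ratio of 8.38 (2.82 to 41.0), or 24.9 without blood 8 and 17.1 without tumor 4. In the lymphocyte lists, 1 of 3 cytotoxic genes fell (camera adjusted p = 0.0116, or adjusted p = 0.119 with an estimated correlation), 2 of 4 naive genes fell (camera adjusted p = 0.0266, or adjusted p = 0.128 with an estimated correlation) and 1 of 4 residency genes, RGS1, rose by 6.24 (camera adjusted p = 0.0951). LDHA (1.54) rose among 9 hypoxia and glycolysis genes (camera adjusted p = 0.298). None passed among 9 MHC class I genes (camera adjusted p = 0.0278, or adjusted p = 0.322 with an estimated correlation), 6 matrix genes, 7 interferon-stimulated genes (camera adjusted p = 0.155 for each) or 28 oxidative phosphorylation genes (camera adjusted p = 0.888), and of 3 red cell and platelet genes PPBP fell (camera adjusted p = 0.0709). CD99 was 1.41 higher on the log2 scale without passing (edgeR adjusted p = 0.0640), EWSR1 was at -0.04 (adjusted p = 0.969), and FLI1 had too few counts to be tested. Calls were lost without tumor 1 for HLA-DQA1, HLA-DRB1, LTB, WARS, CDKN2D, LGALS2, CX3CR1, PLAC8, NCF1 and MNDA, without tumor 3 for the last 5 of these and LDHA, without tumor 4 for LGALS2, without blood 3 or 5 for MNDA, NCF1 and LDHA, without blood 2 for MNDA and without blood 4 for LDHA. With 3 tumors, 1 library weighed heavily: the count of genes was 245 without blood 8 and 95 without blood 5. It was 257 within barcode set 2, with 18 of 20 immediate-early and heat-shock genes up, and 71 with at least 50 cells per library, where 69 rose and 2 fell; that left tumor 4 alone against 3 blood libraries, and the lone tumor is assumed to vary like the blood libraries.

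**Figure D3:**
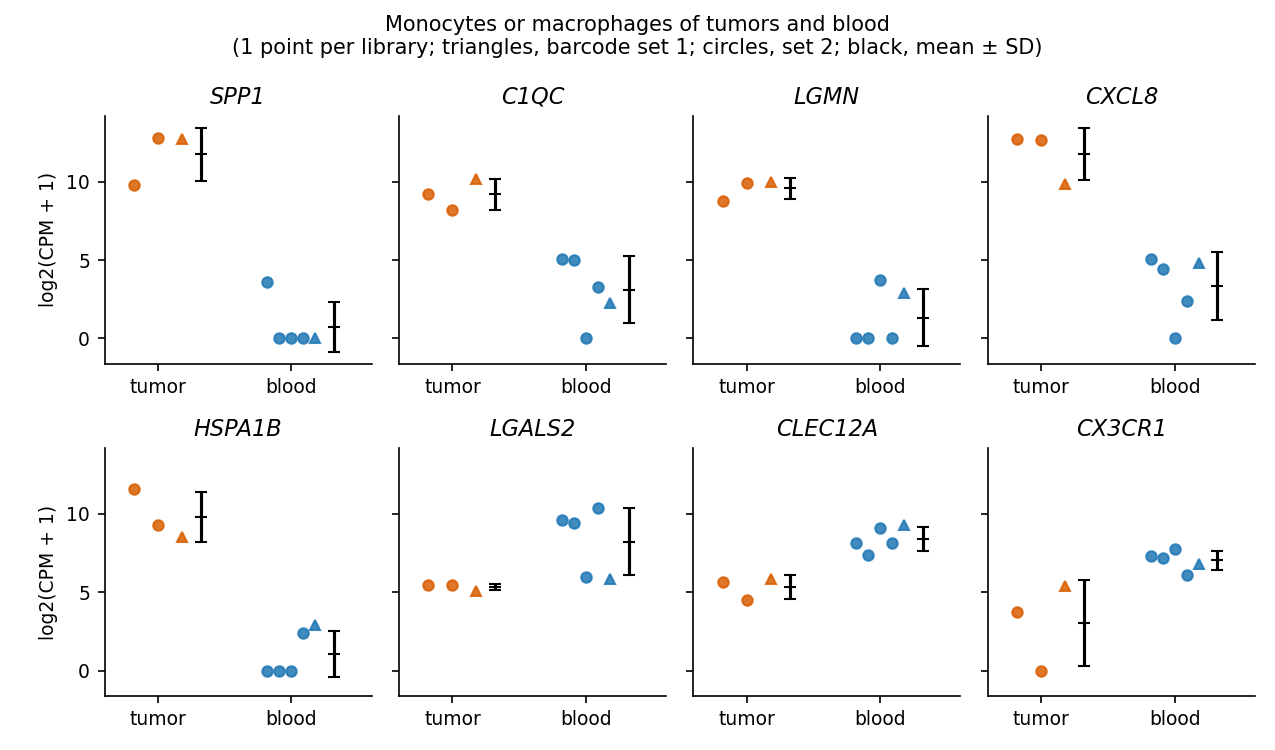
log2(CPM + 1) of 8 genes in monocytes or macrophages summed per library, 3 tumors against 5 blood samples, 1 point per library (triangles, barcode set 1; circles, set 2) with the mean ± SD in black. SPP1, C1QC, LGMN, CXCL8 and HSPA1B rose in tumors and LGALS2, CLEC12A and CX3CR1 fell (edgeR adjusted p below 0.05).

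The study also asked how tumors differ among themselves and how cells differ within a tumor. Between all 7 tumors, Ewing cells varied most in immediate-early and heat-shock genes, at a mean of 7.87 log2 CPM with an SD of 1.33, from 5.33 to 9.52. G2/M genes (4.32, SD 0.96), S phase genes (4.15, SD 0.90), matrix and mesenchymal genes (4.88, SD 0.85) and red cell and platelet genes (SD 0.77) followed. This order rests on single tumors: without tumor 5 the SD of immediate-early and heat-shock genes was 0.792, below G2/M (1.02) and S phase genes (0.974), and without tumor 4 that of red cell and platelet genes was 0.222. The EWSR1::FLI1-activated genes had a mean of 6.80 with an SD of 0.70, from 5.87 to 7.57. MHC class I genes (SD 0.29) and oxidative phosphorylation genes (SD 0.19) varied less. By barcode set, the activated genes were at 7.32 ± 0.33 in set 1 (n = 4) and 6.11 ± 0.26 in set 2 (n = 3), with no overlap (exact permutation test, p = 0.0571, the smallest that 4 against 3 allow, adjusted p = 0.4). Oxidative phosphorylation genes (8.11 against 8.42) and inflammatory cytokine genes (0.78 against 1.71) parted the sets without overlap too, with set 1 lower and the same p. The authors' annotation placed 1.53% to 14.9% of a tumor's Ewing cells in a proliferating subclass.

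**Figure D4:**
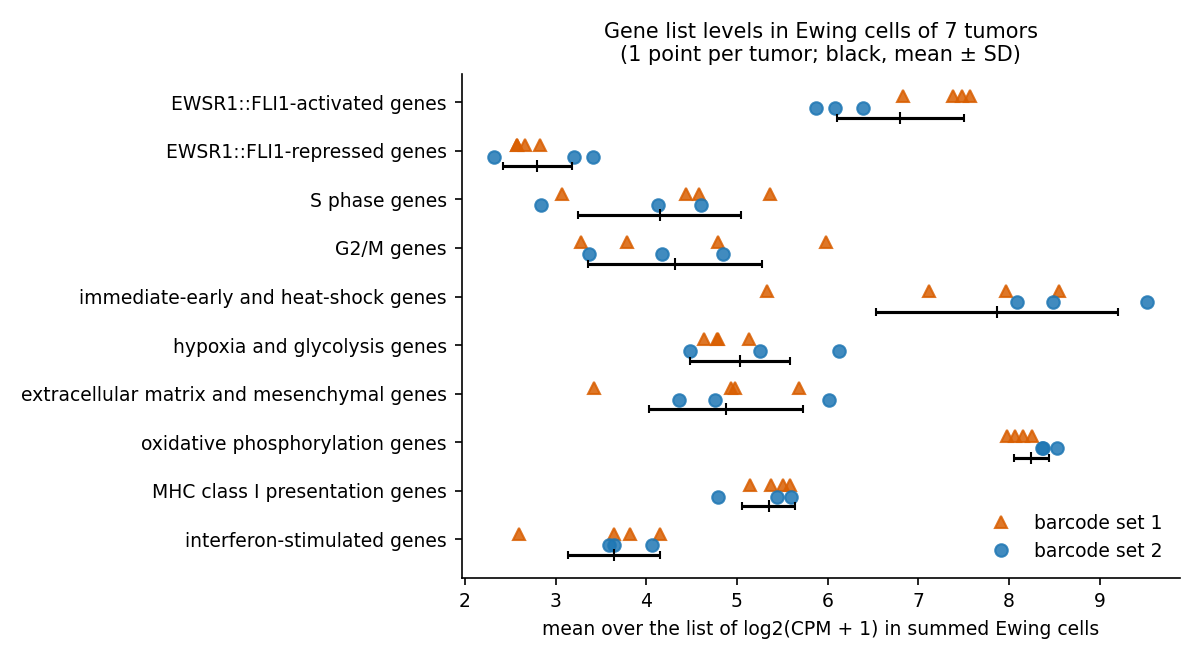
Mean log2(CPM + 1) of the fixed gene lists in Ewing cells, 1 point per tumor (n = 7), colored by barcode set. The immediate-early and heat-shock genes spread from 5.33 to 9.52, and the 2 sets part for the EWSR1::FLI1-activated genes and, with set 1 lower, for oxidative phosphorylation genes.

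The genes that varied most between tumors were FABP7, a fatty acid-binding protein of neural progenitors on chromosome 6 from 122779475 to 122784074, with an SD of 5.48 on the log2 scale and 853 ± 1250 CPM (SD, n = 7), and FN1, fibronectin, with an SD of 4.34. Next were GRP (SD 4.08), gastrin-releasing peptide, SCGB3A2 (3.79), SCG2 (3.79), secretogranin II, and PENK (3.69), proenkephalin. The rest of the 12 were SYNPR (3.68), of synaptic vesicles, PRAC1 (3.62), TSTD1 (3.58), TCIM (3.52), SYCP1 (3.52), of meiotic chromosomes, and TPTE2 (3.41). This order depends on tumors at 0 CPM. With a prior count of 10, the SDs were 2.05 for SYNPR, 2.22 for PRAC1, 2.00 for TSTD1, 2.07 for SYCP1 and 2.13 for TPTE2. Those of RARRES2 (2.72) and TSPAN8 (2.66), not among the 12, were then larger. The median SD of the 2348 genes with a mean of at least 50 CPM was 0.645. EWSR1 was at 60.4 ± 15.7 CPM, FLI1 at 19.4 ± 13.1 and CD99 at 601 ± 221. The latter pair parted the barcode sets without overlap, with means of 29.001 and 737 CPM in set 1 and 6.69 and 421 in set 2. Each tumor is 1 library, so these spreads include differences between libraries.

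Within tumors, rank correlations of the EWSR1::FLI1-activated score with the other lists were described more than tested, because with 6 tumors a single list at the smallest p could not pass after adjustment over 20 lists. In the 6 tumors with enough Ewing cells, its highest mean rank correlation was with MHC class I genes (0.0894, from 0.00136 to 0.198), positive in 6 of 6 tumors (exact sign-flip permutation test, p = 0.03125, the smallest that 6 tumors allow, adjusted p = 0.469 over 20 lists). Random lists gave a mean of 0.0250, and against them p was 0.0625. Interferon-stimulated genes followed with 0.0565 (exact sign-flip permutation test, adjusted p = 0.469), or 0.0211 without tumor 2. Unthinned, the means of these lists were 0.181 and 0.171, positive in 6 of 6 tumors each. In thinned cells the lowest of the means was -0.0398, for G2/M genes, which turned to 0.00389 without tumor 4, to 0.0200 in cells without TOP2A or MKI67 UMIs and to 0.0903 unthinned. Each correlation is across cells of 1 tumor, and cells are not independent replicates.

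The last comparison would have set Ewing cells of blood against those of tumors. Annotated Ewing cells were found in 1 blood library, blood 3, where they were 157 of 882 cells, or 17.8% (exact 95% interval 15.3 to 20.5). The other 7 blood libraries held none, which allows from 0.0835% in blood 8 to 1.89% in blood 7. With 1 library no test was made. The 157 cells had a median of 389 UMIs. The 7 marker genes of Ewing cells had 51 of their 67435 UMIs, 756 CPM, and 0 of the 944476 UMIs of the other 725 cells of that library. Of the 157 cells, 155 had the same barcode as a kept Ewing cell of tumor 3, which came from another patient.

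**Figure D5:**
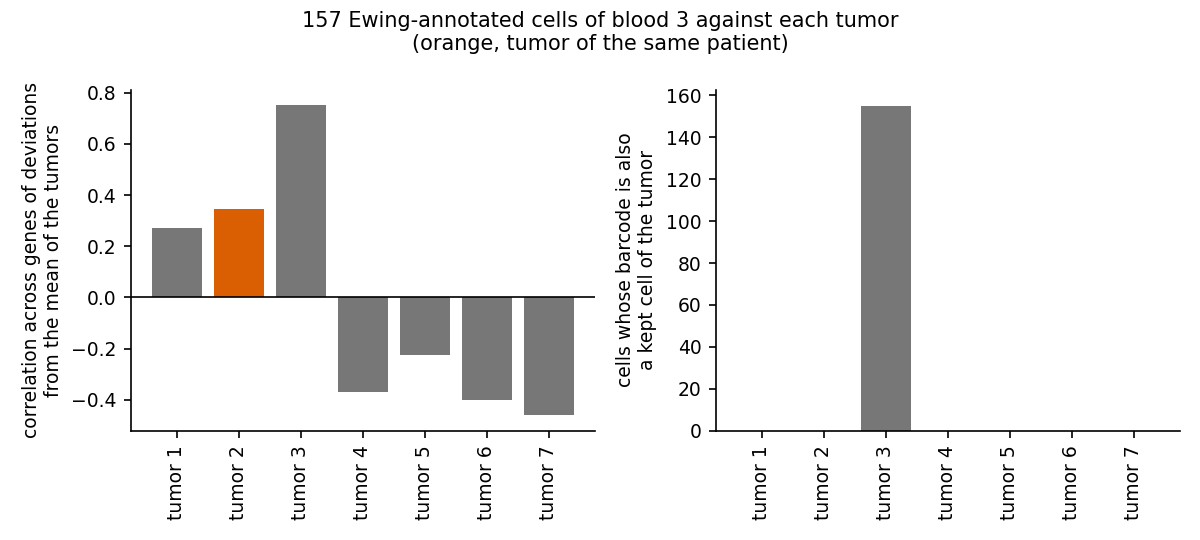
For the 157 Ewing-annotated cells of blood 3, 1 bar per tumor gives the correlation across genes between their summed profile and the tumor's Ewing cells, as deviations from the mean of the tumors, and the number of the cells whose barcode is also a kept cell of that tumor. Tumor 3 had the highest correlation (0.751) and 155 shared barcodes, against 0.344 and 0 for the same patient's tumor, drawn in orange.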

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

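The tests of handling and of activation for the stress genes, and of patient differences for the barcode sets, were chosen after the result was seen, as were the barcode sets themselves. In 55 sets of values searched for a sample far from the others, 10 had one, where chance gives about 2.8 (about 1 set in 20).

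Annotated Ewing cells made up 17.8% of blood 3 and none of the next blood library, and 483 called barcodes were shared by tumor 3 and blood 3, where chance gives 1.67. Circulating tumor cells of the donor would resemble that donor's own tumor, but the summed profile correlated at 0.344 with it and at 0.751 with tumor 3, of another patient. Free RNA would not follow a single tumor cell, yet 12.3 percentage points more of each cell's UMIs lay at genes of its same-barcode tumor cell than at genes of like cells (99.4% against 87.1%). For 154 of the 155 cells with a kept partner, that partner was the most similar of 843 Ewing cells of tumor 3, where chance gives 0.184. The UMIs of these cells were a median of 3.16% of those of the partner. For the 155 cells these values argue against circulating tumor cells of the donor. They would be seen with reads of tumor 3 assigned to blood 3, for example by index hopping.

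Immediate-early and heat-shock genes were higher in T cells and in monocytes or macrophages of tumors than of blood. The barcode set does not account for it, since the T cell median within set 2 was 3.59 on the log2 scale. Free RNA of Ewing cells would give a median of 4.01% of the level seen in tumor T cells. That estimate rests on 0 to 4 marker UMIs in each of tumors 1 to 4 and 75 in tumor 6. It was not made for monocytes or macrophages and does not cover free RNA of other cells. Ewing cells of the tumors carried the list 3.65 above blood T cells. Handling of the tissue, thawing and digestion included, could give this by acting on every cell of the suspension. But cell types differed within blood too, with monocytes at 6.14 ± 0.84 log2 CPM (SD, n = 5) and T cells at 4.22 ± 0.86 (n = 8). In tumors, monocytes or macrophages were at 9.39 ± 0.41 (n = 3) and Ewing cells at 7.87 ± 1.33 (n = 7). The comparison therefore mixes cell type with handling and cannot decide. Activation of the cells in the tissue before sampling cannot be told apart from handling, since no tissue was measured without handling. Ewing cells and the other cells of a tumor differed by a median of 0.10. If handling is the source, FOS, JUN and HSPA1A levels in these tumors may say little about the living tissue. Nor can handling be told apart from the tissue for the other differences between tumors and blood. These include the residency genes and IFNG in T cells and the cytokine genes in monocytes or macrophages.

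Ewing cells of the 4 tumors of barcode set 1 differed from those of the 3 tumors of set 2 at 553 of 13014 genes (edgeR), with 257 higher and 296 lower. No other of the 35 splits of the tumors called more than 1 gene, which argues against chance. The split by total UMIs called 0, but it mixes the sets, and the splits other than the real one had a median of 0. It therefore cannot decide whether depth plays a part. Of the 329 genes called that were also tested in T cells, 94.8% had the same sign of set difference there, with tissue as a term. Of all 4746 genes tested in both, 75.5% did. T cells of the same tumors carried Ewing markers at up to 5.45% of the Ewing level, which could add to the same sign at called genes. The shared sign could come from library chemistry or batch. Differences between the patients' tumors cannot be told apart from it, because each tumor lies in 1 set: of the 2348 genes at 50 CPM or more, 33.0% parted the sets without overlap, where chance gives 5.71%. In the fits with tissue as a term, the set called 1583 genes in T cells and 426 in monocytes or macrophages. Tumor against blood called 328 and 145 in the main tests, which had no term for the set. The lower EWSR1::FLI1-activated level of set 2 could be technical in part.

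Other samples stood far from their group. One blood library, blood 8, had a median of 9.16% mitochondrial counts (next 3.28), T cells at 35.2% of immune cells (next 72.7), monocytes at 55.6% (next 22.5) and dendritic cells at 7.25% (next 1.14). In Ewing cells, 1 tumor was lowest in interferon-stimulated genes at 2.60 (mean log2 CPM, next 3.59), 1 lowest in checkpoint genes at 0.72 (next 1.28) and 1 highest in red cell and platelet genes at 3.30 (next 1.56). In 1 tumor the EWSR1::FLI1-activated score had a rank correlation of 0.230 with interferon-stimulated genes (next 0.0538), and in 1 of 0.305 with tumor-associated macrophage genes (next 0.0344).

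The number of genes called was set against that of other splits of the same libraries. The Ewing comparison called 2696 genes and no other of its 32 splits more than 1 (1 split as large, the real one). The classes were drawn from expression, so this outcome was set beforehand and does not bear on chance. Monocytes or macrophages called 145, and no other of 56 splits more than 1, which argues against chance. T cells called 328, and 3 of 100 splits called as many, the real one included; the others, with 568 and 495, put all 3 libraries of barcode set 1 on one side. Within set 2 alone the tumors and blood differed at 430 genes. No other of 100 splits, drawn from 120, called more than 43, which argues against chance there.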

How the results depend on the processing

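Tests within a barcode set, with the set as a covariate, with cells of 1-library barcodes, with genes high in Ewing cells left out, without a block in the paired patients, of spreads without a tumor, of low counts without a library, and of splits within set 2 were chosen after seeing the data. Of the alternatives to the main results, 326 kept direction and side of the threshold or stayed near the count, 21 moved, 13 lost the call and 5 changed sign. Where the reason is not named, the cause was not tested. No paired analysis was possible because 1 patient alone had enough monocytes or macrophages in both samples, and for Ewing cells of blood because 1 library held them; none of the alternatives planned for the latter was run.

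Among shares, the dendritic difference was -0.566 points with clusters named by markers, where no tumor cluster was dendritic, turned to -2.01 within set 1, and lost its call with the UMI and mitochondrial filter (8.70), within set 2 (12.8, where none could pass) and in the paired block (9.03, 3 pairs, too few to pass). Leaving out a library gave 6.43 to 10.8 and ended the call without tumor 1 (6.43), 3 (7.12) or 4 (7.93) or without any of blood 2 to 7 (7.92 each). Within set 1, T cells turned to 36.9 and monocytes or macrophages to -37.7 points. B cells lay between -0.662 (without tumor 3) and 2.45, T cells between -37.1 and -16.6, monocytes or macrophages between 10.1 and 23.8, and Ewing cells between 73.6 and 82.8; the paired block of Ewing cells gave 69.7 (p = 0.125, the smallest that 4 pairs allow in an exact test).

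Without the filter on low counts 4705, 653 and 576 genes passed for Ewing, T and myeloid cells, as more genes were tested. With at least 50 cells per sum 178 passed for T cells, with 2 tumors left, and 71 for myeloid cells, with 1 tumor left, so the losses there say little of stability. T cells with the patient as a block gave 204, of which 148 were among the 328, and the same patients unblocked 76. The block also ended the calls of ANXA2 (1.08), ISG20 (-0.68), COX4I1 (-0.79) and COX6C (-0.83) and changed no other call of a named gene. Leaving out a library gave 1949 to 2521 genes for Ewing cells, 195 to 779 for T cells (tumor 4 199, blood 2 215, 3 195, 4 210, 5 204, 6 216, 8 779) and 95 to 245 for myeloid cells (blood 5 95, 8 245). The set as a covariate gave 282 and set 2 alone 257 for myeloid cells. With an estimated correlation 4, 5 and 0 lists passed for Ewing, T and myeloid cells. No list score passed in any setting (0 in each), but with 5 tumors, where p is at least 0.0625, or 3 none could, and with 6 only many lists at once.

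Named genes that were past the threshold kept their sign, but of 60, 44 and 35 named genes, passing or not, 4, 13 and 11 lost the call without some library. FLI1 did so in Ewing cells without tumor 2, 3, 4, 6 or 7 (-1.52 to -1.45), with at least 50 cells (-1.46), with 1-library barcodes (-1.37), without the filter (-1.23) and without a block (-1.20, as 7 other named genes), and JCHAIN (-7.52), KLRF1 (-2.63), PF4 (-8.50), S100A8 (-3.86) and S100A9 (-7.87, fitted) in T cells without tumor 6. TIGIT lost it without any of 8 libraries (1.47 to 1.82), ISG20 and COX4I1 without any of 10 and COX6C without any of 11. HLA-DQA1 (1.71), HLA-DRB1 (1.73), LTB (-4.33) and WARS (-3.32) lost it in myeloid cells without tumor 1, and LGALS2 without any tumor (-3.93 to -3.68). With at least 50 cells 12 named T cell genes, IFNG (2.78) and CD69 (1.16) among them, lost the call, as did 14 named myeloid genes with the lone tumor, and 9 named T cell genes lost it within set 2. CD99 in myeloid cells passed with DESeq2 (1.46), with its size factors (1.46), with the covariate (1.38) and without blood 8 (1.53), and EWSR1 in Ewing cells with DESeq2 (-0.52). Genes not past the threshold changed sign near 0. CD99 was at -0.0237 without a block in Ewing cells, and in T cells at -0.0303 without the filter and -0.0639 with 50 cells. FLI1 in T cells was at -0.167 without the filter, -0.0639 in the patient block, -0.209 unblocked, -0.382 with the set as a covariate and -0.0547 to 0.431 without a library. EWSR1 in myeloid cells was at 0.0849 with DESeq2, 0.0486 with its size factors, 0.104 with 1-library barcodes, 0.00511 with the covariate and -0.276 to 0.240 without a library.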

Other observations

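No test here was planned; the values below describe annotation and scores as the authors gave them. Subclasses of tumor T cells parted by barcode set. In set 2 tumors 86 of 87 T cells were tissue resident memory cells, while in set 1 tumors 164 of 401 were CD8 effector cells, 149 CD4 cells with IL7R, 49 resident memory and 39 regulatory T cells. In blood the T class held 1882 naive cells and 724 cytotoxic T or natural killer cells in set 2, and 680 and 557 in blood 8. Tumor macrophages with CD14 and complement genes were 45 of 88 myeloid cells in set 2 and 41 of 86 in set 1, and inflammatory monocytes with IL1B were 37 and 19.

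Proliferating cells, as annotated, made up 12.8% and 14.9% of the Ewing cells of tumors 2 and 4, 5.63% of those of tumor 1 and between 1.53% and 2.27% in the other 4. Osteoclasts, which resorb bone, were 20 cells in 3 tumors, and endothelial cells were seen in 6.

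The authors' score of the EWS program averaged 0.905 ± 0.689 in the 4 tumors of set 1 and -0.650 ± 0.415 in the 3 of set 2. Their oxidative phosphorylation score went the other way, -0.382 against 0.522, as did their ribosome score, -0.990 against 0.538. Each p was 0.0571 in an exact permutation test, the smallest that 4 against 3 allow (adjusted p = 0.114 over 6 scores). The same sign of set difference as in Ewing cells was seen in monocytes or macrophages at 83.0% of the 135 called genes tested in both, against 65.4% of all 1756 genes tested in both.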
